A study of Rattus norvegicus with 8 samples.

How the data were processed

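RNA of 8 rat kidney allografts, 2 per group, was hybridised to 1-colour Agilent whole-genome arrays after labelling of 1 µg of total RNA with Cy3, per the labels' protocols. Each array was scanned and quantified with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited files give, per spot, a processed signal intensity that the software had background-subtracted and detrended within the array, per the file headers, with low signals replaced by surrogate values and no scaling between arrays. They also give the raw mean and local background intensity and flags for outlier spots, saturation and signal well above background. The authors' deposited value table holds intensities on a linear scale, and for every probe with 1 spot its values were the processed signal times 1 factor per array, to within 0.01 log2 units, except for 1338 zeros, all at spots flagged as non-uniform. Its column medians lay between 105.7 and 106.9, and how the factor was chosen is not given in the sources used here. No per-sample column was left unmapped (0 columns).

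From the processed signals, control spots and spots flagged as outliers were left out, the log2 signals of the 10 spots of each of 263 replicated probes were averaged, and each array's 75th percentile was subtracted. Of 41012 probes, 765 had no unflagged spot on some array and were left out. A probe was tested where it was well above background on both arrays of at least 1 group, which 11561 probes were not. The remaining 28686 probes stood for 24451 genes, each represented by the probe with the highest mean over the 8 arrays, and 11869 of these genes carried a gene symbol. Probe names came from the files and were updated through a table of RefSeq genes of the GRCr8 assembly: 10861 probes matched by accession, 5542 by symbol and 3704 by synonym, and 20905 kept the name in the files. The files' probe positions name no genome build, so no coordinates are given. Saturated spots were kept.

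Groups came from the sample labels. The comparisons were high minus low difference, each treatment minus untreated high difference, the treatments against each other and each treatment minus low difference. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend) in a single fit of all 8 arrays, which left 4 residual degrees of freedom, to which the fit added 2.37 prior ones. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. With 2 arrays against 2, a two-sided exact permutation test cannot give a p below 0.33, so none was used. A log2 difference is given with its moderated standard error, and a group mean with its SD.

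For a probe not well above background on either array of a group, a bound replaces the fold. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own level and the lowest level among probes well above background. No fold is given where that bound is under 1. A bound holds for the main processing, and some alternatives gave smaller differences. Levels of different probes were not set against each other.

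The 24 gene lists were fixed before the data were examined. They cover IL-6/STAT3 and acute-phase genes, chemokines, endothelial activation, interferon response, tubular injury, nephron segments, podocytes, endothelium, leukocyte classes, red blood cells, MHC, glucocorticoid response, cell cycle, complement, heat shock and unfolded protein response, hypoxia, matrix, growth hormone/IGF axis, vasoactive genes and neighbouring tissues. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. No list passed with an estimated correlation, or with fry, in any of the 6 comparisons. The rule for naming genes and the alternatives were fixed at the same time. Among genes with a symbol whose arrays did not overlap between the groups, the rule took in each comparison the 6 genes each way with the largest difference among those passing, filled by the smallest p where fewer passed. It added the followed genes Il6, Il6r, Il6st, Socs3, Stat3, Nr3c1, Fkbp5, Tsc22d3, Havcr1, Lcn2, Spp1, Timp1 and Ccl2. For the comparisons with low-difference grafts and between treatments, these genes could be left out of the text. List examples came from the 4 members of a list with the smallest p. Some genes that the rule took are not reported here.

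Covariances between contrasts were set beside those of 1000 simulated draws of unchanged groups that shared the same arrays and had each gene's pooled variance. Genes were drawn independently, so the draws do not show how far 1 deviating array can move the covariance of correlated genes. For the alternatives the no-change value was the mean gene variance divided by the number of high-difference arrays. The methods were tested on simulated data with the real genes' means and spreads and 200 changed genes in the comparison of anti-IL6R with untreated high-difference grafts, over 24451 genes. Limma called 1.49% of genes changed by 1 log2 unit, 46.3% of those changed by 2 and 89.4% of those changed by 4, with 1 false call among 24251 unchanged genes. Alternatives covered scaling, background correction, the deposited value table, filters, probe rules, the variance prior, the samples in the fit, a block for the replicate number, thresholds and leaving out each array. Normexp background correction added an offset of 50 to the signals, which by itself shrinks the log2 differences of dim probes. Array slides were read from the file headers, and a slide block could not be fitted between treated and untreated grafts.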

Results

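Gene expression was measured in rat kidney allografts collected 24 h after transplantation. Kidneys of Dark Agouti donors were placed into Lewis recipients, which carry a different major histocompatibility complex (MHC), after 25 min of cold storage at 4 °C. The 8 arrays fell into 4 groups of 2 biological replicates. In the high-difference group the donor weighed 20 to 50% less than the recipient, and in the low-difference group 0 to 20% less. Recipients of 2 further groups of high-difference grafts received 500 µg of an antibody blocking the interleukin-6 receptor (anti-IL6R) or 15 mg/kg of the glucocorticoid prednisolone directly after surgery. The share of gene spots well above background was 66.5% and 65.3% on the high-difference arrays and 64.5% on the second prednisolone array, against 70.2% on the first and 71.5% to 74.1% on the low-difference and anti-IL6R arrays. The 3 arrays with the lowest shares were also the ones on which T and NK cell genes lay, in the median, below their mean over the 8 arrays. The number of arrays limits the precision of every value below.

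On the first principal component, which held 39.0% of the variance, the untreated high-difference arrays scored -32.3 and -93.5. The low-difference arrays scored 45.3 and 19.0 and the anti-IL6R arrays 33.8 and 17.5. The prednisolone arrays lay far apart, at -42.1 and 52.3, and correlated with each other across genes at r = 0.956, against 0.992 for the anti-IL6R pair. They also lay apart for the chemokine gene Ccl2, with log2 levels of 4.21 and 0.86. Its mean on the anti-IL6R arrays was 3.07 ± 0.16 (SD, n = 2). All arrays of the untreated groups lay on 1 slide and all arrays of the treated groups on another, so a difference between treated and untreated grafts cannot be told apart from a difference between slides.

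The comparison of high-difference with low-difference grafts asked how the donor-recipient weight difference altered the graft early after surgery. Genes of T and NK cells were lower in the high-difference grafts, with a median log2 difference of -1.53 and values below 0 for 32 of 32 tested members. Genes of monocytes, macrophages and dendritic cells had a median of -1.45, with 28 of 33 below 0, and interferon-response genes a median of -0.75, with 30 of 34 below 0. Genes of tubular injury and repair lay the other way, at a median of 1.06 with 26 of 29 above 0. These lists passed camera with its preset correlation (adjusted p = 1.1e-16, 2.2e-08, 5.8e-09 and 0.00013), and none passed once the correlation was estimated (adjusted p = 0.43, 0.43, 0.43 and 0.45 with an estimated correlation). The estimated correlations between members were 0.56, 0.86, 0.58 and 0.49. The preset of 0.01 treats members as nearly independent, and every call at the preset correlation rests on it. With normexp background correction the T and NK cell, monocyte and interferon medians were -0.41, -0.84 and -0.37, and these lists still passed camera with the preset correlation.

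Among single genes, limma called 0 of 24451 at an adjusted p under 0.05 for high minus low, with 3589 at an unadjusted p under 0.05, where 1223 would arise by chance. The 2 groups did not overlap for 56.5% of the genes, against 33.3% by chance. The genes named in this paragraph had the smallest p in their direction and did not pass. Zbp1, an interferon-induced sensor of nucleic acids, had a log2 level of -4.76 ± 0.32 (SD, n = 2) in high-difference and -1.70 ± 0.05 in low-difference grafts, a difference of -3.06 ± 0.33 (SE, adjusted p = 0.21). Cxcl9, a chemokine that draws activated T cells, differed by -2.90 ± 0.34 (SE, adjusted p = 0.21). Under the alternatives the difference ranged from -3.29 to -1.5 for Zbp1 and from -3.37 to -1.57 for Cxcl9. The leptin receptor gene Lepr was at least 2.04-fold and the cytokine-like gene Cytl1 at least 1.21-fold higher in the low-difference grafts, because both were not well above background in the high-difference grafts (adjusted p = 0.21 and 0.096). Acp4 was at least 1.1-fold higher there as well, and Rgs17 was too close to background for a fold. Under the alternatives the log2 differences of Lepr, Cytl1 and Acp4 shrank to as little as -0.32, -0.24 and -0.1, which is under these bounds. On the high side stood Chac1, a glutathione-degrading enzyme of the amino acid stress response, at 3.39 ± 0.42 (SE, adjusted p = 0.21). Beside it stood Cntf, a cytokine of the interleukin-6 family, at 1.67 ± 0.21. Srxn1 and Nqo1, both targets of the oxidative stress factor NRF2, had differences of 1.88 ± 0.27 and 2.32 ± 0.36, and the growth factor gene Nrg1 of 1.33 ± 0.22. Guca1a was at least 3.38-fold higher in the high-difference grafts, but its log2 difference fell to 0.82 under an alternative, which is under this bound.

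Within the T and NK cell list, 20 members were lower when adjusted over the list alone, and 0 over all genes tested. The antigen receptor component Cd3d differed by -1.38 ± 0.25 (SE, n = 2 per group), and the cytotoxic granule gene Gzmb was at least 2.55-fold higher in low-difference grafts, although a second probe of Gzmb pointed the other way. Because 9 members were not well above background in one of the groups, the median was also taken with these at their bound. With 2 further members, dim in both groups, left out, that median was -1.32. In the monocyte list, Csf1r, the receptor that macrophages need to survive, differed by -2.09 ± 0.50 and the costimulatory gene Cd86 by -1.51 ± 0.26, with 1 member lower when adjusted over the list alone. In the interferon list, 2 members were lower when adjusted over the list alone. MHC and antigen presentation genes had a median of -0.42 with 29 of 32 below 0 (adjusted p = 8.3e-07, and 0.43 with an estimated correlation), among them the class II gene RT1-Da at -2.16 ± 0.49. Chemokine genes had a median of -0.83 (adjusted p = 2.5e-05, and 0.43 with an estimated correlation), among them Ccl19 at -3.18 ± 0.86. B and plasma cell genes had a median of -0.90 over 7 members (adjusted p = 0.025, and 0.43 with an estimated correlation), but of 0.48 over those well above background on all arrays and of -0.13 with normexp, and did not pass in either case (adjusted p = 0.85 and 0.22), nor without the second low-difference array or either prednisolone array (adjusted p = 0.056 and 0.088). Neutrophil genes had a median of -0.31 and did not pass (adjusted p = 0.29).

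Genes of the nephron and its vessels were also lower. The loop of Henle, distal tubule and collecting duct list had a median of -0.83, with 32 of 37 below 0, and the proximal tubule list a median of -0.95, with 39 of 52 below 0 (adjusted p = 8.3e-07 and 1.5e-05, and 0.43 for both with an estimated correlation). The growth factor gene Egf, made in the distal tubule, differed by -4.90 ± 1.68 (SE, n = 2 per group), the water channel gene Aqp2 by -2.53 ± 0.83 and the phosphate transporter gene Slc34a1 by -2.73 ± 0.80. The phosphate and urate transporter gene Slc17a3 of the same proximal list lay the other way, at 1.26 ± 0.24. Endothelial cell genes had a median of -0.59, endothelial activation and adhesion genes of -0.88, podocyte genes of -0.50 and renin-angiotensin and vasoactive genes of -0.83 (adjusted p = 8.3e-07, 0.0011, 9e-04 and 5.3e-05, and 0.43 for each with an estimated correlation). The podocyte median shrank to -0.29 under a processing alternative. Extracellular matrix genes had a median of -0.35 and complement and coagulation genes of -0.24 (adjusted p = 0.0018 and 0.028, and 0.51 and 0.56 with an estimated correlation), the latter of 0.03 with normexp. Without the second low-difference array the endothelial activation, extracellular matrix and complement lists did not pass, at -0.58, -0.11 and -0.09 (adjusted p = 0.056, 0.51 and 0.33). The matrix list was also lost without the second high-difference array, at -0.22 (adjusted p = 0.098), and the complement list without the first high-difference array or either prednisolone array, at -0.30 and -0.24 (adjusted p = 0.10 and 0.09).

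Of the tubular injury list, the keratin gene Krt20 was at least 43.8-fold higher in the high-difference grafts (adjusted p = 0.30), and the scaffold gene Akap12 differed by 2.92 ± 0.82. The adhesion gene Vcam1, also in this list, lay the other way, at -1.87 ± 0.51. No member passed when adjusted over the list alone. Havcr1, which encodes the injury marker KIM-1, was left out of the fit because its probe was flagged on the second high-difference array. Its log2 level was 7.43 on the first high-difference array, against 3.79 and 5.24 on the low-difference arrays. IL-6/STAT3 and acute-phase genes had a median of 0.72, with 19 of 25 above 0 (adjusted p = 0.046, and 0.66 with an estimated correlation), and this call was lost under every processing alternative run, with adjusted p from 0.056 (quantile normalization) to 0.16 (no filter on dim probes) at the preset correlation. It was also lost without the second high-difference array, at 0.37, and without the first low-difference array, at 0.48 (adjusted p = 0.33 and 0.37). Il6 itself was well above background on 1 array alone, of the prednisolone group, and was not tested. Of the other genes followed in every comparison, Lcn2 differed by 2.56 ± 0.97 (SE), Timp1 by 1.39 ± 0.86, Socs3 by 1.18 ± 0.61, Stat3 by 0.37 ± 0.24 and Spp1 by 0.27 ± 0.30. Il6st, the shared receptor subunit gp130, differed by -0.60 ± 0.21, Il6r by -0.31 ± 0.45, Nr3c1 by -0.34 ± 0.22, Fkbp5 by -0.16 ± 0.21, Tsc22d3 by -0.18 ± 0.41 and Ccl2 by -1.15 ± 1.06. None of these 11 genes passed, with adjusted p of at least 0.32. The lists of glucocorticoid-responsive, growth hormone/IGF, neighbouring tissue, cell cycle, heat shock and unfolded protein response, hypoxia and red blood cell genes did not pass, with medians of 0.00, -0.13, -0.35, 0.34, 0.04, 0.18 and -0.32, but the cell cycle median turned to -0.54 without the first low-difference array (adjusted p = 0.00021). Of the 16 lists that passed in high minus low, 11 kept direction and call in all 8 fits with 1 array left out and under all 7 processing alternatives at the preset correlation. With 1 array left out, the proximal tubule median then ranged from -1.33 to -0.47 and the MHC median from -0.61 to -0.23. The tubular injury median ranged from 0.69 to 1.6 in those fits. Leaving out an array of a treated group, or adding a block for the replicate number, cannot move a median of this comparison. Such fits could test the call alone. Leaving out 1 array at a time gave between 0 and 39 called genes, the most without the first high-difference array, and 28 without either prednisolone array.

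**Figure D1:**
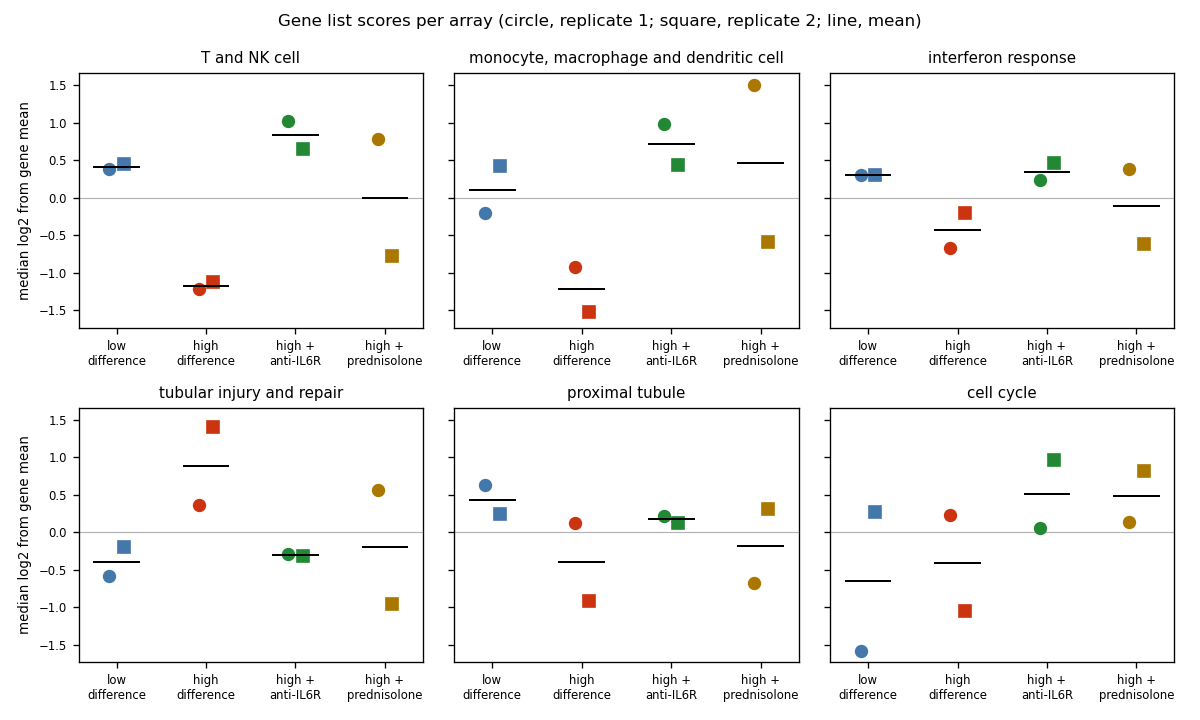
Score of 6 gene lists on each array, as the median over the list of the log2 level minus the gene's mean over the 8 arrays (vertical axis, log2 units) for the 4 groups (horizontal axis). Circles and squares are replicates 1 and 2 and lines their mean; the T and NK cell score was -1.22 and -1.12 on the high-difference arrays and 0.38 and 0.45 on the low-difference arrays.

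The comparison of anti-IL6R-treated with untreated high-difference grafts asked what blockade of the interleukin-6 receptor altered. T and NK cell genes were higher in the treated grafts, at a median of 2.09 with 32 of 32 above 0, as were monocyte, macrophage and dendritic cell genes, at 1.96 with 33 of 33 above 0. MHC and antigen presentation genes had a median of 0.69 with 32 of 32 above 0, and interferon-response genes of 0.79 with 31 of 34. Tubular injury genes had a median of -0.96 with 27 of 29 below 0. All 5 passed camera with the preset correlation (adjusted p = 9.2e-21, 1.8e-15, 1.7e-11, 1.3e-10 and 0.00038), and none with an estimated one (adjusted p = 0.33, 0.33, 0.33, 0.33 and 0.44 with an estimated correlation). The T and NK cell median was 0.60 with normexp and 1.22 over members well above background on all arrays, and the interferon median 0.46 with normexp, and these passed camera with the preset correlation.

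For anti-IL6R minus high, limma called 0 of 24451 genes, with 4334 at an unadjusted p under 0.05, of which 1736 were higher and 2598 lower in treated grafts. By chance 1223 would arise. The 2 groups did not overlap for 59.8% of the genes, against 33.3% by chance. When adjusted over the list alone, 25 members of the T and NK cell list, 10 of the monocyte list, 11 of the interferon list and 5 of the MHC list were higher. Cxcl9 differed by 3.43 ± 0.34 (SE, n = 2 per group, adjusted p = 0.12), reaching a log2 level of -1.28 ± 0.11 (SD). Under the alternatives its difference ranged from 2 to 3.66. Zbp1 differed by 2.72 ± 0.33, RT1-Da by 2.61 ± 0.49 and Csf1r by 2.45 ± 0.50. Gzmb was at least 5.30-fold and the T cell adhesion gene Cd2 at least 2.01-fold higher in treated grafts, since both were not well above background in untreated ones. With the 11 such members of the T and NK cell list at their bound, its median was 1.37. Other genes with the smallest p, none of which passed, were the sodium channel gene Scn4a, at least 1.11-fold higher, and Ttc41, at least 1.2-fold higher. Under the alternatives their log2 differences fell to as low as 0.08 and 0.05, which is under these bounds. On the low side stood Chac1 at -3.04 ± 0.42 (SE, adjusted p = 0.15), Cntf at -1.56 ± 0.21, Stx3 at -1.11 ± 0.17 and Syt12 at -1.74 ± 0.24. Exph5 was at least 2.91-fold higher in untreated grafts, but its log2 difference shrank to -1.19 under an alternative, which is under this bound. Il10ra and Or14j5b were too dim in untreated grafts for a fold above 1.

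Endothelial cell genes had a median of 0.74 with 13 members higher when adjusted over the list alone, among them Tie1 at 1.53 ± 0.24, and extracellular matrix genes a median of 0.83 (adjusted p = 1.3e-10 and 1.7e-07, and 0.33 for both with an estimated correlation). Chemokine genes had a median of 1.46, endothelial activation genes of 1.11, renin-angiotensin genes of 0.59, neutrophil genes of 0.67 and B and plasma cell genes of 0.95 (adjusted p = 5e-08, 0.00024, 0.00024, 0.00046 and 0.029, and 0.33 for each with an estimated correlation). The chemokine median fell to 0.91 under a processing alternative. The cell cycle, proximal tubule and distal nephron lists had medians of 0.93, 0.66 and 0.48 (adjusted p = 0.00024, 0.00065 and 0.003, and 0.55, 0.47 and 0.55 with an estimated correlation), and the cell cycle list did not pass without the second high-difference or the second anti-IL6R array, at 0.22 and 0.46 (adjusted p = 0.18 and 0.16), nor the proximal tubule list without the former, at 0.07 (adjusted p = 0.29). Complement, podocyte and glucocorticoid-responsive genes had medians of 0.39, 0.31 and 0.14 (adjusted p = 0.0037, 0.0079 and 0.038, and 0.44, 0.44 and 0.35 with an estimated correlation). Without the first anti-IL6R array the distal nephron, podocyte and glucocorticoid-responsive lists did not pass, at 0.29, -0.02 and -0.02 (adjusted p = 0.059, 0.23 and 0.33), and the last was lost without 5 further arrays in turn. Over members well above background on all arrays the B and plasma cell median was -0.65 (adjusted p = 0.91), and that list was also lost with normexp and without either prednisolone array (adjusted p = 0.35 and 0.10). With normexp the neutrophil, B and plasma cell, complement, podocyte and glucocorticoid-responsive medians lay between -0.03 and 0.10. Heat shock and unfolded protein response genes had a median of -0.31 (adjusted p = 0.0079, and 0.33 with an estimated correlation), with 4 members lower when adjusted over the list alone, but of -0.11 with quantile normalization and -0.26 with normexp, and did not pass in either (adjusted p = 0.22 for both). Random lists matched on mean expression had a median of -0.22, and the heat shock median a percentile of 15.07 among them. It was therefore not unusual for genes of that brightness. IL-6/STAT3 and acute-phase genes had a median of -0.34 and did not pass (adjusted p = 0.43). Of that list, the copper carrier gene Cp differed by 1.80 ± 0.42 and the fibrinogen gene Fga by -2.77 ± 0.99. Socs3, the feedback inhibitor induced by STAT3, differed by -0.60 ± 0.61 (SE), Stat3 by -0.25 ± 0.24, Il6st by 0.55 ± 0.21, Il6r by 0.32 ± 0.45, Lcn2 by -1.66 ± 0.97, Spp1 by -0.47 ± 0.30, Timp1 by -0.80 ± 0.86 and Ccl2 by 1.79 ± 1.06. Nr3c1, Fkbp5 and Tsc22d3 differed by 0.41, 0.12 and -0.31, and none of the 11 followed genes passed. Of the 19 lists that passed in anti-IL6R minus high, 12 kept direction and call in all these fits and alternatives, although the neutrophil median ranged from 0.32 to 1.45 with 1 array left out. Fits without a low-difference or prednisolone array could not move these medians. Leaving out either prednisolone array gave 169 called genes, and leaving out the first high-difference array gave 51.

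The comparison of prednisolone-treated with untreated high-difference grafts asked what the steroid altered. Monocyte, macrophage and dendritic cell genes were higher in the treated grafts, at a median of 1.66 with 33 of 33 above 0, and T and NK cell genes at a median of 1.22 with 29 of 32 above 0. Tubular injury genes had a median of -0.93 with 24 of 29 below 0, and IL-6/STAT3 and acute-phase genes of -0.87 with 20 of 25 below 0. These passed camera with the preset correlation (adjusted p = 8.5e-16, 2.1e-13, 0.0055 and 0.0079) but not with an estimated one (adjusted p = 0.53, 0.53, 0.56 and 0.56 with an estimated correlation). The T and NK cell median was 0.57 with 10 members that were not well above background in one of the groups at their bound. It was 0.32 with normexp and 0.78 over members well above background on all arrays, and the list passed camera with the preset correlation in both. Glucocorticoid-responsive genes had a median of -0.09, a test direction upward and an adjusted p of 0.62.

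For prednisolone minus high, limma called 0 of 24451 genes, with 2892 at an unadjusted p under 0.05, where 1223 would arise by chance. The 2 groups did not overlap for 38.9% of the genes, against 33.3% by chance. Neither T and NK cell nor monocyte genes passed when adjusted over the list alone. Among the genes with the smallest p, none of which passed, the macrophage gene Ms4a7 was at least 42.6-fold, the odorant receptor gene Or7g35 at least 2.46-fold and the chemerin receptor gene Cmklr1 at least 1.18-fold higher in treated grafts. Under the alternatives the log2 differences of Ms4a7, Or7g35 and Cmklr1 fell to as low as 3.06, 0.67 and 0.03, which is under these bounds. Medag differed by -2.18 ± 0.24 (SE, n = 2 per group, adjusted p = 0.22), the activin antagonist gene Fst by -2.37 ± 0.29, Cntf by -1.61 ± 0.21 and Slc17a3 by -1.70 ± 0.24. Or11g1 and Guca1a were at least 2.24-fold and 2.36-fold higher in untreated grafts, but their log2 differences shrank to as little as -0.54 and -0.73 under the alternatives, also under these bounds. Scn4a, Cytl1 and Acp4 were too dim for a fold. Fga differed by -3.27 ± 0.99, the protease inhibitor gene A2m by -2.50 ± 0.81 and the oncostatin receptor gene Osmr by -1.27 ± 0.49. Chac1 differed by -2.58 ± 0.42 and Cxcl9 by 1.93 ± 0.34. Fkbp5 and Tsc22d3, both direct glucocorticoid receptor targets, differed by 0.35 ± 0.21 (SE) and -0.08 ± 0.41, and a second probe of Tsc22d3 had the opposite sign. Nr3c1, which encodes that receptor, differed by 0.42 ± 0.22. Socs3 differed by -1.40 ± 0.61, Lcn2 by -2.07 ± 0.97, Spp1 by -0.93 ± 0.30, Timp1 by -1.47 ± 0.86, Ccl2 by 1.26 ± 1.06, Il6r by 0.35 ± 0.45, Il6st by -0.04 ± 0.21 and Stat3 by -0.27 ± 0.24.

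Endothelial cell genes had a median of 0.67, cell cycle genes of 0.91, chemokine genes of 0.65 and podocyte genes of 0.43 (adjusted p = 3.8e-09, 8.2e-05, 0.00017 and 0.00026, and 0.53, 0.56, 0.56 and 0.53 with an estimated correlation). Distal nephron, interferon and MHC genes had medians of 0.42, 0.10 and 0.24 (adjusted p = 0.0013, 0.0013 and 0.017, and 0.56, 0.56 and 0.68 with an estimated correlation). Heat shock and unfolded protein response genes had a median of -0.22 (adjusted p = 0.0055, and 0.53 with an estimated correlation). Random lists matched on mean expression had a median of -0.15, and the heat shock median a percentile of 18.45 among them. It was therefore not unusual for genes of that brightness. Endothelial activation, extracellular matrix, neutrophil, renin-angiotensin and B and plasma cell genes had medians of 0.79, 0.45, 0.44, 0.17 and 0.68 (adjusted p = 0.002, 0.001, 0.0044, 0.019 and 0.016, and 0.53, 0.56, 0.56, 0.56 and 0.53 with an estimated correlation), and each lost its call without 1 array or more. Without the first prednisolone array the chemokine, interferon and MHC lists did not pass, at -0.02, -0.18 and -0.18 (adjusted p = 0.77, 0.73 and 0.15). Without the second the distal nephron and heat shock lists did not, at -0.35 and -0.12 (adjusted p = 0.34 and 0.30), nor the cell cycle list without the second high-difference array, at 0.19 (adjusted p = 0.17), nor the interferon list without the first high-difference array, at -0.09 (adjusted p = 0.36). With normexp the podocyte and interferon medians were 0.11 and 0. The T and NK cell score was 0.78 on the first and -0.78 on the second prednisolone array. The list's median was 0.51 without the first and 1.96 without the second prednisolone array, and the monocyte median 0.67 and 2.69. The injury list no longer passed without the second, at -0.36, or without the second high-difference array, at -0.67 (adjusted p = 0.61 and 0.17). The IL-6/STAT3 list likewise did not pass without either of these arrays, at -0.32 and -0.46 (adjusted p = 0.80 and 0.11). Of the 17 lists that passed in prednisolone minus high, those of T and NK cells, monocytes, endothelial cells and podocytes alone kept direction and call in every fit with 1 array left out. The count of called genes was 223 without the first and 21 without the second prednisolone array, and 36 without the first high-difference array.

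**Figure D2:**
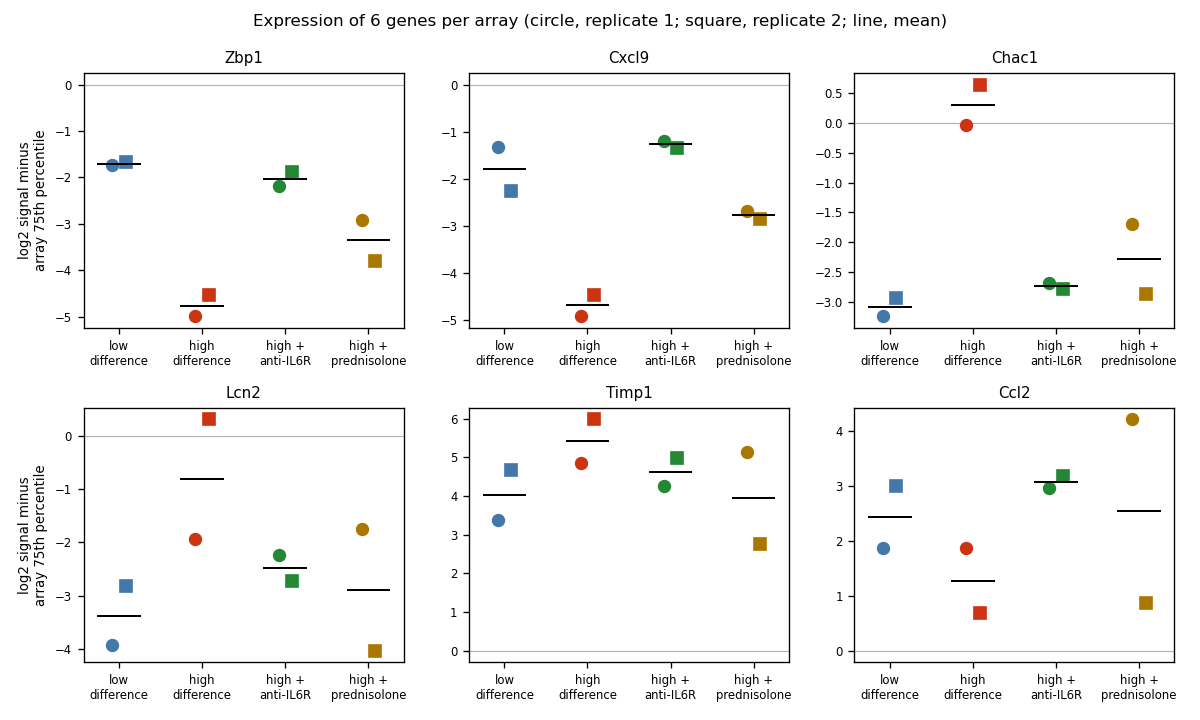
Log2 signal minus the array's 75th percentile (vertical axis) of Zbp1, Cxcl9, Chac1, Lcn2, Timp1 and Ccl2 on each array of the 4 groups (horizontal axis). Circles and squares are replicates 1 and 2 and lines their mean; for Chac1 the high-difference mean was 0.30, against -3.09, -2.74 and -2.28 in the low-difference, anti-IL6R and prednisolone groups.

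To set the treatments against the effect of weight difference, the log2 differences of all 24451 genes were compared between contrasts. The anti-IL6R differences had a covariance of -0.390 with the differences of high minus low, where sharing the untreated high-difference arrays alone gave -0.113 in simulation. The prednisolone differences had a covariance of -0.278 with them, again against -0.113. The anti-IL6R and prednisolone differences had a covariance of 0.336 with each other, against 0.113. Both of these contrasts set the same slide against the other, which the simulation does not hold. A slide difference would therefore raise this covariance and cannot be told apart from a shared effect of the treatments. The correlations across genes, which are not independent replicates, were -0.82, -0.67 and 0.78, against -0.50, -0.50 and 0.50 in simulation. The high-difference group had too few arrays to be split between the contrasts, and part of each excess can come from the shared arrays. Without the second high-difference array the covariances were -0.274, -0.193 and 0.236, against no-change values of -0.231, -0.231 and 0.231. Set against these, the excess was small or absent. The no-change values take in the wide spread between the prednisolone arrays, so they cannot decide how much excess was left.

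Between the treatments, anti-IL6R-treated grafts had higher MHC and antigen presentation genes than prednisolone-treated ones, at a median of 0.66 with 31 of 32 above 0, higher T and NK cell genes at 0.81 with 31 of 32, and higher interferon-response genes at 0.61 with 31 of 34. These passed camera with the preset correlation (adjusted p = 1.1e-14, 7.6e-12 and 5.9e-10) and not with an estimated one (adjusted p = 0.64 for each with an estimated correlation). With normexp the T and NK cell and interferon medians were 0.25 and 0.29. Both groups lay on the same slide. The other 8 lists passed at the preset correlation alone, not with an estimated one, and had medians from 0.21 to 0.61. None of the 11 kept its call in every fit with 1 array left out. For anti-IL6R minus prednisolone limma called 0 of 24451 genes, with 833 at an unadjusted p under 0.05, fewer than the 1223 that would arise by chance. The 2 groups did not overlap for 26.2% of the genes, against 33.3% by chance. Without the second prednisolone array the MHC, T and NK cell and interferon lists did not pass, with medians of 0.21, 0.02 and 0.08. Leaving out either prednisolone array gave some called genes.

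Against low-difference grafts, cell cycle genes were higher in both treated groups, at a median of 1.23 with 41 of 43 above 0 after anti-IL6R and of 1.13 with 40 of 43 above 0 after prednisolone (adjusted p = 1.3e-14 and 3.1e-10, and 0.85 and 0.96 with an estimated correlation). Both treated groups lay on another slide than the low-difference grafts. The differences in this paragraph therefore cannot be told apart from a difference between slides. After anti-IL6R, monocyte genes had a median of 0.44 and T and NK cell genes of 0.47 (adjusted p = 1.5e-05 and 0.00047, and 0.85 for both with an estimated correlation), and neutrophil genes of 0.69 with 14 of 15 above 0 (adjusted p = 0.00014, and 0.85 with an estimated correlation). After prednisolone, proximal tubule genes had a median of -0.70 with 49 of 52 below 0, and interferon-response genes of -0.28 (adjusted p = 5.3e-06 and 0.00029, and 0.96 for both with an estimated correlation). Limma called 0 of 24451 genes in either comparison, with 753 at an unadjusted p under 0.05 for anti-IL6R minus low and 1473 for prednisolone minus low. In each, 1223 would arise by chance. The groups did not overlap for 39.3% and 31.6% of the genes, against 33.3% by chance. Without the first low-difference array the cell cycle medians were 0.22 and 0.16 and neither passed (adjusted p = 0.12 and 0.16). The T and NK cell list after anti-IL6R did not pass over members well above background on all arrays, at 0.33, or without the first anti-IL6R array, at 0.24 (adjusted p = 0.21 and 0.058), and had a median of 0.08 with normexp. The monocyte list did not pass without the first low-difference array, at 0.32 (adjusted p = 0.05). The interferon list after prednisolone turned to 0.13 without the second prednisolone array and did not pass (adjusted p = 0.50). Of the 12 lists passing in anti-IL6R minus low, the neutrophil list alone kept direction and call in every fit with 1 array left out. Its median then ranged from 0.28 to 0.85, and it was as low as 0.14 under a processing alternative. Of the 9 in prednisolone minus low, the proximal tubule list alone kept direction and call in those fits, with medians from -1.13 to -0.21. Leaving out either prednisolone array gave 8 called genes for anti-IL6R minus low, and 151 (without the first) and 32 (without the second) for prednisolone minus low.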

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

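All alternatives here were chosen with the design, and none after the result was seen. Replicate numbers are shared between groups without a stated pairing, and the deviations of same-numbered arrays correlated between -0.35 and 0.37, so the numbers were not taken as pairs. With the replicate number as a block, limma called 0 genes in all 6 comparisons. A slide block was not run, since it changes nothing where both groups share a slide and cannot be estimated where they do not. Where an array is left out, its partner is assumed to vary like the other groups.

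Of the 132 counts of called genes under alternatives, 103 were 0 like the main count and 29 were not. Those that also required a 2-fold difference were fixed at 0 by the main counts. The deposited value table, with 1 factor per array and near-equal medians, gave the same counts as scaling to the median. Quantile normalization gave 3 called genes for high minus low, 7 for anti-IL6R minus high, 4 for prednisolone minus high, 2 for anti-IL6R minus prednisolone and 4 for anti-IL6R minus low. Scaling to the median and the deposited value table each gave 1 for high minus low and 1 for anti-IL6R minus high. An adjusted p under 0.1 gave 2, 5 and 3 for high minus low, anti-IL6R minus high and anti-IL6R minus low. Keeping flagged spots gave 1 for anti-IL6R minus prednisolone and 1 for prednisolone minus low. With 1 array left out, the counts ranged from 0 to 39 for high minus low, 0 to 169 for anti-IL6R minus high, 0 to 223 for prednisolone minus high, 0 to 130 for anti-IL6R minus prednisolone, 0 to 8 for anti-IL6R minus low and 0 to 151 for prednisolone minus low. In comparisons without the prednisolone group, dropping either prednisolone array left the differences unchanged and gave equal counts. The 1 array left adds nothing to the pooled variance. The mean gene variance divided by the number of high-difference arrays then fell from 0.113 to 0.0714. These higher counts therefore came from the smaller variance. In the main fit the spread between the prednisolone arrays raises the standard errors of these comparisons. The cause of the other changes was not tested.

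The shared high-difference arrays alone fix the sign of the covariances, so each is set against its no-change value, which was added for the alternatives after the result was seen. With normexp background correction those of anti-IL6R and of prednisolone minus high with high minus low were -0.194 and -0.131, against -0.0627, and that between the treatments 0.153, against 0.0627. With 1 array left out they ranged from -0.72 to -0.274, from -0.576 to -0.178 and from 0.236 to 0.65. Without the second high-difference array they were -0.274, -0.193 and 0.236 against -0.231, -0.231 and 0.231, with little or no excess over these values. The no-change values take in the spread between the prednisolone arrays, so they cannot decide how much excess was left. Without the first they were -0.72, -0.576 and 0.65 against the same values. The cause was not tested.

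Of 1290 values of named genes under alternatives, 11 reversed and 36 passed where the reported value did not. Normexp turned Il10ra to -0.11 and Or14j5b to -0.12 in anti-IL6R minus high, and Cytl1 to -0.02 and Acp4 to -0.03 in prednisolone minus high, all of them dim. Quantile normalization turned Spp1 to 0.08 in anti-IL6R minus high. With 1 array left out, Fkbp5 ranged from -0.38 to 0.06 and Tsc22d3 from -0.62 to 0.27 in high minus low. Socs3 ranged from -1.33 to 0.14 and Fkbp5 from -0.10 to 0.34 in anti-IL6R minus high, and Il6r from -0.30 to 1.0 and Ccl2 from -0.42 to 2.93 in prednisolone minus high. The cause was not tested.

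Of 2448 list results under alternatives, 2080 kept direction and call, 70 passed where the reported one did not, 258 no longer passed, which includes every call with an estimated correlation and with fry, and 40 reversed in median or in the direction of the test. Fits without an array of a group not compared, the replicate block, the estimated correlation and fry left the medians as they were, so these could test the call alone. The deposited value table nearly repeats scaling to the median. With normexp, complement turned to 0.03 and growth hormone/IGF genes to 0.13 in high minus low, and glucocorticoid-responsive genes to -0.03 in anti-IL6R minus high. With probes well above background on all arrays, B and plasma cell genes turned to 0.48 in high minus low, -0.65 in anti-IL6R minus high and -0.56 in prednisolone minus high. The other 34 arose with 1 array left out, 24 of them a prednisolone array, and the medians then had these ranges. In anti-IL6R minus high they were -0.02 to 0.24 for glucocorticoid-responsive genes and -0.02 to 0.68 for podocytes. In prednisolone minus high they were -1.58 to -0.32 for IL-6/STAT3 genes, -0.18 to 0.62 for interferon response, -0.35 to 1.18 for distal nephron, -0.18 to 0.71 for MHC, -0.34 to 0.78 for proximal tubule, -0.02 to 1.54 for chemokines, -0.41 to 0.43 for complement and -1.50 to -0.36 for tubular injury. In anti-IL6R minus prednisolone they were -0.45 to 0.37 for cell cycle, -0.33 to 1.52 for chemokines, 0.02 to 0.86 for complement, -0.28 to 1.05 for IL-6/STAT3 genes, -0.77 to 0.73 for distal nephron, -0.72 to 1.24 for monocytes, -0.10 to 0.89 for proximal tubule, -0.01 to 0.39 for renin-angiotensin genes and -0.85 to 0.52 for tubular injury. In prednisolone minus low they were -1.05 to 0.82 for chemokines, -0.77 to 0.14 for complement, -0.45 to 0.54 for extracellular matrix, -0.77 to 0.42 for IL-6/STAT3 genes, -0.83 to 0.13 for interferon response, -1.23 to 0.32 for distal nephron, -0.82 to 0 for MHC, -0.74 to 1.32 for monocytes, -1.11 to 0.38 for T and NK cells, -0.44 to 0.11 for renin-angiotensin genes and -0.33 to 1.03 for tubular injury. In high minus low the range was -0.54 to 1.25 for cell cycle genes. The cause was not tested.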

Other observations

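The tests of the 3 patterns weighed here were chosen after the result was seen. Chac1, Trib3, Atf4 and Asns, genes of the amino acid stress response, were the 4 genes of the heat shock and unfolded protein response list with the smallest p in high minus low. Their log2 differences were 3.39 ± 0.42 (SE, n = 2 per group), 2.76 ± 0.47, 1.09 ± 0.25 and 1.87 ± 0.40, while the list's median was 0.04. These 4 members were higher when adjusted over the list alone, and Herpud1, named after its value was seen, was lower, at -1.1 ± 0.29. Limma called 0 members over all genes tested. Of the growth hormone/IGF list, Igf1 differed by -1.60 ± 0.35 and Igfbp3 by -2.67 ± 0.60 in high minus low, and no member passed when adjusted over the list alone.

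The prednisolone arrays stood on opposite sides for several lists. The tubular injury score was 0.57 on the first and -0.96 on the second, the monocyte score 1.51 and -0.59, the neutrophil score 0.66 and -0.78, and the distal nephron score -0.75 and 0.80. Havcr1 had log2 levels of 6.95 and 2.01 on them, and 3.56 and 5.49 on the anti-IL6R arrays.

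The first pattern weighed was the lower T and NK cell list in high-difference than in low-difference grafts, both on 1 slide. A bias that depends on probe brightness was argued against as the whole cause, since the list's median of -1.53 had a percentile of 0 among 10000 random lists matched on mean expression, although the high-difference arrays had fewer spots well above background and normexp background correction cut the median to -0.41, with the list still passing. A single deviating array was argued against too, since leaving out each of the 4 arrays in turn left a median no nearer to 0 than -1.55. For an equal loss of leukocytes of every kind, the neutrophil list's median exceeded that of T and NK cells by 1.22 (interval from resampled genes 0.75 to 2.09). This cannot decide the question, because the interval holds no spread between grafts and treats correlated members as independent. What stays open, and was not tested, is a difference tied to the weight difference, in T and NK cells alone or in leukocytes more widely. Monocyte genes had a median of -1.45. The T and NK cell list did not pass camera with an estimated correlation (adjusted p = 0.43 with an estimated correlation).

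The second pattern was the higher T and NK cell list in treated than in untreated high-difference grafts. A slide effect that depends on brightness was argued against as the whole cause, since the lower of the percentiles for anti-IL6R and prednisolone among the matched lists was 100. That percentile has the limits given for the first pattern. With normexp, however, the medians fell from 2.09 to 0.60 and from 1.22 to 0.32. The offset of that correction shrinks the differences of dim probes whatever their cause, so this fall cannot decide how far brightness is at work. A part due to brightness stays open. The list still passed there at the preset correlation. With an estimated correlation it did not pass in either comparison. A slide effect on these genes themselves could be at work and cannot be told apart from treatment, because no treated group shares a slide with an untreated one. Within the slide of the treated grafts the list differed by 0.81 between anti-IL6R and prednisolone, and by 0.02 without the second prednisolone array, which leaves the question open.

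The third pattern was the distance of the untreated high-difference pair from the other 6 arrays. Of the 28 ways to set 2 arrays against 6, only 1, the real one, gave as many as 5572 genes at an unadjusted p under 0.05, and the highest of the others was 5362, for the second high-difference array with the first prednisolone array. At an adjusted p under 0.1 that other pair gave 1243 genes against 645 for the real one. Because the pair was chosen after it was seen to stand apart and the order depends on the threshold, chance is not excluded. The other pair also has the 2 lowest scores on the first principal component.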
